A study of Homo sapiens with 12 samples.

How the data were processed

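RNA from 6 human neuroblastoma cell lines, with 2 biological replicates per line, was sequenced in 12 libraries. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase, ERCC spike-in RNA was added, and libraries were made from polyA RNA with the KAPA mRNA Hyper Prep kit and sequenced on a HiSeq instrument with reads of 40 bases. The submitters' processing notes name Bowtie2 2.3.4.3, Subread, featureCounts and the build GRCh38. Strand use in counting, multimapping reads and duplicate reads are not given in the sources used here. The deposited values are log2(TPM + 1): undoing the log2 gives values that total 1000000 per library over the listed genes, so TPM was set by the authors over these genes. The table lists no ERCC entry (0) and no mitochondrially encoded gene (0).

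Depth was read from the values themselves. With the summed exon lengths of GENCODE release 29, which gave a length for 19422 genes by gene symbol, values of up to 20 reads stepped in whole reads, within 0.1 read, for 91.0% to 92.1% of these low values per library. The recovered totals were 4327031 to 7590311 reads per library. A floor of 3 reads per library, averaged over the group, was used as the bound where all libraries of a group were at 0, and covers counting error only. Gene positions are those of GENCODE release 29 on GRCh38 and were used for symbols given by the table. Genes that overlap, and families of near-identical genes such as HLA, MICA with MICB, and RAET1 with ULBP, can share or lose reads.

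The comparisons, tests, named genes, gene lists and most alternatives were fixed before the data were examined. Genes with at least 1 TPM in at least 2 libraries were tested (16002 genes). Deposited log2 values with their pseudocount of 1 were fitted with limma 3.58.1 with an intensity trend, in R 4.3.3. For the lineage comparison the 2 libraries of a line were averaged and 3 mesenchymal line means were compared with 3 adrenergic line means, since the lineage belongs to the line. SH-SY5Y-LDK-resistant and SH-EP were each compared with SH-SY5Y in a fit of all 12 libraries with 1 mean per line, so that the spread between duplicates was pooled over 6 lines. These tests measure duplicates of 2 lines and say nothing about other lines. For MYCN, line means of 2 amplified and 4 non-amplified lines were compared with lineage as a covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Errors beside fold changes are limma's standard errors and errors beside TPM are standard deviations of 2 libraries.

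The genes named were those of the largest change among called genes (6 in each direction, with a mean of at least 5 TPM in the higher group and no overlap between groups), up to 4 called members of each list or, where none was called, 2 members of the highest mean, and 26 genes fixed in advance. For MYCN they were the called genes of the largest change, up to 3 in each direction, with MYCN and its neighbours. Of the genes that meet this rule a part is printed. Gene lists, 33 in number, were written from general knowledge. They cover adrenergic and mesenchymal transcription factors, catecholamine and neuronal genes, matrix, cytoskeleton, YAP and TAZ targets, MHC class I and II, interferon response, nucleic acid sensing, natural killer ligands, cytokines, checkpoints, NF-kB, Polycomb, receptor tyrosine kinases, RAS and MAPK output, MYC targets, neighbours of MYCN, proliferation, cholesterol, drug efflux and lysosomes, ATF4 stress and hypoxia. Lists of neural crest, leukocyte, endothelial, epithelial and adrenocortical markers served as checks for other cell types. Ribosomal protein, replication histone and mitochondrially encoded genes served as checks of RNA quality. The 31 lists with at least 3 tested members were tested with limma's camera with a preset correlation of 0.01, and p was adjusted over these lists within a comparison. Members are also counted after adjustment over each list alone.

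Alternatives were a pseudocount of 0.1, no filter and a filter of 5 TPM, quantile normalization, scaling by the median of ratios, rescaling to a fixed total, limma without the trend, no minimum fold change, a replicate block, leaving out each library and each line, a correlation between duplicates (duplicateCorrelation), the spread between duplicates alone, only the 4 libraries compared, camera with an estimated correlation, and fry, which tests a list by itself. Chosen after the data were seen were an estimate of reads before collapsing by start position, duplicateCorrelation with a replicate block, the 4 lines from 4 patients, each comparison with SH-SY5Y against its own SH-SY5Y library, and camera on 12 libraries. Rescaling on ERCC entries was not run because none is listed. Replicate numbers do not pair libraries of different lines: deviations of duplicates correlated between lines at −0.065 to 0.067.

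The fits were tested on simulated data. With 100 genes changed by 1.5 on the log2 scale and 100 by 3, the lineage fit recovered 36 and 73 with 4 false calls among 16002 genes, and the fit of the resistant line recovered 98 and 100 with 3 false calls. The changed genes had a mean log2 value of at least 3, so recovery of lower genes was not tested. The simulated lines were independent, so the false calls of the lineage fit do not cover lines that share a tumour. In a simulation with 1 shifted list camera called that list and 0 of the other lists. The simulated genes varied independently, so this could not show false calls of lists whose genes are correlated. Overlap of the calls of the resistant line and SH-EP was compared with 20 simulations of unchanged groups set against the SH-SY5Y libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.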

Results

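The transcriptomes of 6 human neuroblastoma cell lines were measured by RNA sequencing, with 2 biological replicates per line and 12 libraries in all. Neuroblastoma is a childhood tumour of the sympathetic nervous system, and its cells occur in an adrenergic state, close to sympathetic neuroblasts, and in a mesenchymal state, close to neural crest-derived mesenchyme. The labels call 3 lines adrenergic (Kelly, SH-SY5Y and NBL-S) and 3 lines mesenchymal (CHP-212, SH-EP and SH-SY5Y-LDK-resistant). The last of these is a derivative of SH-SY5Y that was kept in 1.5 µM ceritinib (LDK378), an inhibitor of the receptor tyrosine kinase ALK. SH-SY5Y and SH-EP are both subclones of the SK-N-SH line, so 3 of the 6 lines trace back to a single tumour. The MYCN oncogene is labelled amplified in Kelly and CHP-212 and not amplified in the other 4 lines. Values were deposited as log2(TPM + 1), where TPM is a gene's share of the library's transcripts scaled to 1000000, and 16002 genes passed the filter on low values.

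Depth differed between libraries. Low values stepped in whole reads for 91.0% to 92.1% of the genes examined, within a tolerance of 0.1 read, and the reads recovered from these steps ranged from 4327031 in NBL-S replicate 1 to 7590311 in SH-EP replicate 2. Duplicates of a line correlated across genes with r between 0.986 and 0.991. Between lines the lowest correlation was 0.692, for NBL-S and SH-EP, and the highest was 0.878. Kelly with NBL-S and SH-SY5Y with its resistant derivative both gave that highest value. The resistant line correlated with SH-EP at 0.872. The highest value of any library was 799.1 TPM, and the 10 highest genes held 0.52% to 0.69% of the total, so the top of the scale was narrow.

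The first comparison asked which genes separate the mesenchymal from the adrenergic lines, with the line as the unit of replication (n = 3 lines against 3). The fit treated the line means as independent. SH-SY5Y, its resistant derivative and SH-EP come from the same tumour, and the p-values do not account for that relation. Called genes of the catecholamine and neuronal lists were all lower in the mesenchymal lines. A smaller number of genes was higher, among them CD109, CAV1, AXL and 4 interferon-stimulated genes. The neuroendocrine granule protein SCG3 was lower by 6.65 on the log2 scale (log2 fold change −6.65 ± 0.48 SE, limma adjusted p = 0.00736), and so was the neuronal RNA-binding protein ELAVL3 (−6.65 ± 0.43, adjusted p = 0.0063). CD109, a membrane glycoprotein, showed the largest increase (6.51 ± 0.50, adjusted p = 0.00741), from 1.00 TPM on average in the adrenergic libraries to 175 TPM in the mesenchymal ones. ALK itself was lower by 5.80 ± 0.41 (adjusted p = 0.0066), with 116 ± 4.36 TPM in Kelly (SD, n = 2) and 2.13 ± 0.584 TPM in SH-EP. In all, 61 genes were called higher and 204 lower among 16002 tested, at an adjusted p under 0.05 and a log2 fold change of at least 1.

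The other genes with the largest decreases were INSM2 (−6.62), SEZ6L (−6.55), DPYSL5 (−6.51) and CPLX2 (−6.42), of which CPLX2 encodes a complexin of synaptic vesicle release. The other large increases were those of CAV1, the caveolar coat protein (6.10), MYOF (6.05), SLC25A43 (5.74), the receptor tyrosine kinase AXL (5.68) and FXYD5 (5.53). Of all tested genes 16.9% separated the 6 mesenchymal from the 6 adrenergic libraries without overlap. A gene can separate only 1 of the 10 splits into 3 lines and 3, so the mean share over splits is at most 10%. Genes are correlated, so a single split can exceed that mean by chance.

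Among 20 transcription factors of the adrenergic state, 6 were lower and none was higher, and 8 were lower when adjusted over the list alone. HAND1 (−6.12 ± 0.94) and TFAP2B (−5.86 ± 0.59) fell, whereas HAND2 (−0.66, adjusted p = 0.0588) and GATA3 (−0.37, adjusted p = 0.604) did not pass. HAND2 lay between 212 and 399 TPM in every line, and GATA3 between 202 and 493 TPM. Of 15 genes of catecholamine synthesis and storage 8 fell, and 9 did when adjusted over the list alone. They included DDC (−6.42), SLC18A1 (−6.34), CHGA (−5.86) and DBH (−5.26 ± 0.32, adjusted p = 0.0063), the enzyme that makes noradrenaline. TH, which catalyses the first step of the pathway, followed the lines rather than the lineage: it stood at 294 ± 4.05 TPM in Kelly and 147 ± 0.217 TPM in CHP-212, and at 6.38 ± 0.325 TPM or less in the other lines (−1.41 ± 2.5, adjusted p = 0.795). Without Kelly the lineage difference of TH was 0.65. Kelly and CHP-212 are also the 2 lines labelled MYCN-amplified, so TH was high in the lines with that label. In the comparison by that label 0 genes were called higher, and MYCN itself was not called. That comparison therefore cannot decide whether TH goes with the label. Of 20 neuronal genes 4 fell (9 when adjusted over the list alone), among them DCX (−6.33), STMN4 (−4.89) and SYP (−4.59). These 3 lists were called lower by camera with its preset correlation (adjusted p = 2.8e-09, 8.34e-11 and 5.24e-10). None of the calls held with an estimated correlation (adjusted p = 0.209, 0.209 and 0.177 with an estimated correlation).

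Of 24 transcription factors of the mesenchymal state, 4 were higher and none lower (5 higher when adjusted over the list alone). RUNX2 (5.06 ± 0.66), TBX18 (4.33 ± 0.69), the AP-1 subunit FOSL1 (4.32 ± 0.66) and ELK4 (1.06 ± 0.16) rose, and the list was called (adjusted p = 2.12e-08, but adjusted p = 0.258 with an estimated correlation). PRRX1 was high in SH-EP (346 ± 21.4 TPM) and the resistant line (112 ± 4.98 TPM) and low in CHP-212 (2.26 ± 0.426 TPM), so that its difference of 4.82 ± 1.75 was not called (adjusted p = 0.249). NOTCH2 (4.34 ± 1.60, adjusted p = 0.256) and YAP1 (4.51 ± 1.16, adjusted p = 0.145) did not pass either. NOTCH2 already stood at 122 ± 1.75 TPM in SH-SY5Y. The lineage labels may themselves rest on genes of these 2 regulator lists, so their counts are not independent evidence of a direction. Of 21 genes of the cytoskeleton and epithelial-mesenchymal transition 3 rose: CAV1, ANXA1 (5.02) and TWIST2 (4.76). Adjusted over the list alone there were 5. The test gave an adjusted p of 5.06e-06, and adjusted p = 0.394 with an estimated correlation. VIM (1.22 ± 0.49, adjusted p = 0.292) was not called. No member of the 25 matrix and adhesion genes was called, with or without adjustment over the list alone. COL3A1 differed by 3.06 ± 1.08, SPARC by 1.12 ± 0.31, FN1 by 1.39 ± 1.74 and CD44 by 2.88 ± 0.73. FN1 stood at 8.16 ± 1.24 TPM in CHP-212, below Kelly at 36.8 ± 0.926 TPM. That list was nevertheless called as a set (adjusted p = 7.29e-06, and adjusted p = 0.394 with an estimated correlation). Of 20 targets of YAP and TAZ 1 rose, AXL, and 3 did when adjusted over the list alone (adjusted p = 4.04e-05, and adjusted p = 0.394 with an estimated correlation).

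Few immune genes were called between the lineages. Of 35 interferon-stimulated genes 4 rose and none fell: GBP1 (4.71 ± 0.64), IFIT3 (4.18 ± 0.50), IFI35 (3.72 ± 0.54) and IFIT2 (3.30 ± 0.54). Adjusted over the list alone, 10 were higher and 2 lower. Of 16 sensors of foreign nucleic acid 1 rose, the double-stranded RNA receptor TLR3 (3.73 ± 0.46, adjusted p = 0.0191), from 0.25 TPM on average in the adrenergic libraries to 15.9 TPM in the mesenchymal ones. Adjusted over the list alone there were 4. Of 20 genes of MHC class I presentation none was called over all genes and 10 were higher when adjusted over the list alone. HLA-C differed by 3.34 ± 1.09 (adjusted p = 0.214), HLA-B by 1.54 ± 0.61 and B2M, the class I light chain, by 0.58 ± 0.16. The peptide transporter TAP1 differed by 2.25 ± 0.69 and NLRC5, the class I transactivator, by 2.41 ± 0.73. The immunoproteasome subunit PSMB9 was at 0 in every adrenergic library and at 2.17 TPM on average in the mesenchymal ones, at least 2.3-fold higher, and was not called. The chaperones CALR (0.03 ± 0.08) and CANX (0.14 ± 0.10), which have the highest values of the list, did not differ beyond their spread. These 3 immune lists were called higher (adjusted p = 2e-06, 8.05e-05 and 7.37e-09). None held with an estimated correlation (adjusted p = 0.394, 0.214 and 0.343 with an estimated correlation). Reads of HLA-B, HLA-C and MICA can be shared between near-identical genes and depend on the alleles a line carries, and PSMB8, PSMB9 and TAP1 overlap or adjoin on chromosome 6, so values of these single genes are uncertain.

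Ligands for natural killer cell receptors were called as a list of 19 (adjusted p = 0.00156, and adjusted p = 0.394 with an estimated correlation). None of them passed over all genes and 1 did when adjusted over the list alone. MICA was at 0 in all 6 adrenergic libraries, at 28.4 ± 1.70 TPM in SH-EP, 2.44 ± 1.20 TPM in the resistant line and 0.383 ± 0.0207 TPM in CHP-212 (adjusted p = 0.339). ULBP3 differed by 2.04 ± 0.85 (adjusted p = 0.3) and PVR by 0.55 ± 0.27. The 18 cytokines and chemokines and the 15 NF-kB targets were also called (adjusted p = 0.00339 and 0.00883, and adjusted p = 0.394 with an estimated correlation for both). Each had 0 called members over all genes and 1 higher when adjusted over the list alone. TGFB1 differed by 1.43 ± 0.28, CSF1 by 2.03 ± 0.62 and NFKB1 by 0.59 ± 0.22. The 16 genes of drug efflux and lysosomes were called higher (adjusted p = 8.05e-05, and adjusted p = 0.345 with an estimated correlation). None of these passed over all genes and 3 did when adjusted over the list alone. LAMP2 differed by 0.75 ± 0.16 and CTSB by 0.50 ± 0.38. Of 20 outputs of RAS and MAPK signalling FOSL1 and PHLDA1 (2.04 ± 0.32) rose (adjusted p = 0.044, and adjusted p = 0.604 with an estimated correlation). Of 20 proliferation genes and 25 MYC targets none was called, with or without adjustment over the list alone, while both lists were called lower as sets (adjusted p = 0.00383 and 0.0174, and adjusted p = 0.604 with an estimated correlation for both). Their members moved little: MKI67 differed by −0.32 ± 0.14, TOP2A by −0.16 ± 0.16 and NOLC1 by −0.19 ± 0.15.

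Of the remaining lists, only that of epithelial markers was called. Of 12 immune checkpoint genes 1 fell, CD200 (−5.53 ± 0.63), and CD274, which encodes PD-L1, differed by 2.24 ± 1.45 (adjusted p = 0.477). Of 19 receptor tyrosine kinases AXL rose and ALK fell, and 2 were higher and 3 lower when adjusted over the list alone. No member was called among 11 genes of Polycomb repressive complex 2, with EZH2 at −0.32 ± 0.20 (adjusted p = 0.459). None was called among 6 MHC class II genes (CTSS 2.58 ± 0.65), 8 genes at or near MYCN on chromosome 2, 19 cholesterol genes, 14 genes of the ATF4 stress response or 14 hypoxia genes. Markers of other cell types were measured beside these groups. Of 7 epithelial markers none passed over all genes and 2 did when adjusted over the list alone, and the list was called (adjusted p = 0.0496, and adjusted p = 0.394 with an estimated correlation). KRT8 differed by 4.55 ± 0.89 and KRT18 by 4.0 ± 1.05. No member was called among 11 neural crest and Schwann markers (SNAI2 2.81 ± 0.73, NGFR −1.70 ± 2.31), 10 leukocyte markers (LCP1 −3.10 ± 1.78) or 7 endothelial markers (EMCN 2.44 ± 1.71). Among the signs of RNA quality, none of 20 ribosomal protein genes and none of 10 replication-dependent histone genes was called. A list's median, mean and test differed in sign only where the list was not called, as for the receptor tyrosine kinases here (median 0.31, mean −0.24, tested as lower). Of the 8 adrenocortical markers only 2 passed the filter on low values and no mitochondrially encoded gene is listed, so neither list was tested in any comparison.

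The lineage calls depended on which lines were present. Without NBL-S limma called 0 genes (1841 had an unadjusted p under 0.05), without SH-EP 0 higher and 19 lower, without Kelly 8 and 42, without the resistant line 22 and 106, without SH-SY5Y 230 and 262, and without CHP-212 73 and 244. In the 4 lines that come from 4 different patients (Kelly, NBL-S, CHP-212 and SH-EP) 0 genes passed and 2204 had an unadjusted p under 0.05. The fold changes behind the lost calls stayed large: without NBL-S ALK lay at −5.74, DBH at −5.32, ELAVL3 at −6.43 and DCX at −6.08 (each at adjusted p = 0.0738), and in the 4 lines ALK at −5.66 and ELAVL3 at −6.63 (each at adjusted p = 0.11). The calls of FOSL1, IFIT2 and HAND1 were also lost when single libraries were left out, again because the adjusted p crossed the threshold. HAND1 lay at −5.96 (adjusted p = 0.0543) without CHP-212 replicate 2 and FOSL1 at 4.51 (0.054) without Kelly replicate 2. IFIT2 lay at 3.42 (0.0523) without SH-SY5Y replicate 2 and at 3.19 (0.062) without NBL-S replicate 1. With a pseudocount of 0.1, which widens the fold changes of low genes by construction, calls were lost in the same way for FOSL1 (4.54, adjusted p = 0.0513), TBX18 (4.59, 0.0539), GBP1 (6.25, 0.0506), IFIT2 (3.77, 0.0525), DDC (−7.61, 0.0525), HAND1 (−6.71, 0.0525), MYOF (7.04, 0.0618), AXL (6.21, 0.0625) and TWIST2 (6.31, 0.0993).

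**Figure D1:**
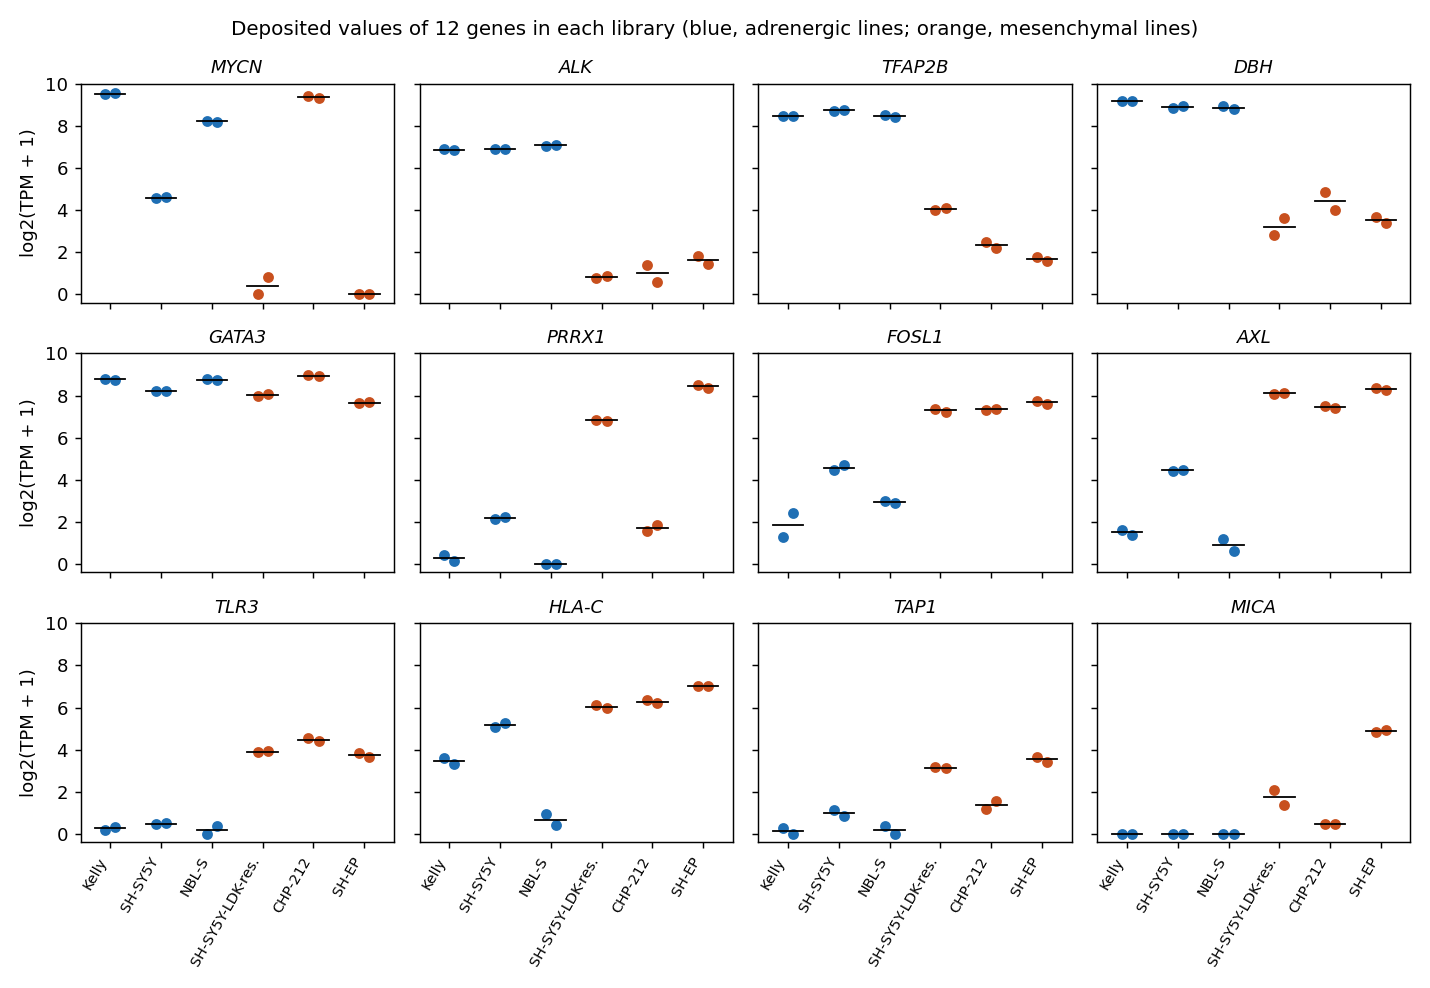
Deposited log2(TPM + 1) values of 12 genes (vertical axis) in the 6 lines (horizontal axis), with 1 point per library and a bar at the mean of each line's 2 libraries. ALK and DBH separate the 3 adrenergic lines (blue) from the 3 mesenchymal lines (orange), and PRRX1 is at 112 TPM in the resistant line but low in CHP-212.

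The second comparison set SH-SY5Y-LDK-resistant against its parent SH-SY5Y (n = 2 libraries each, with the spread pooled over all 6 lines), and asked how a line grown under an ALK inhibitor differs from the line it came from. The labels give ceritinib for the resistant line only, and the lineage label differs as well. Effects of the drug, of the derivation of the line and of its lineage state therefore cannot be told apart here. Most of the catecholamine and neuronal genes examined were lower in the resistant line, and many interferon-stimulated and MHC class I genes were higher. The homeodomain factor DRGX was at 146 TPM in SH-SY5Y and at 0 in both resistant libraries, at least 162-fold lower against the floor of 3 reads per library. ALK, the target of the drug, fell by 6.10 ± 0.23 on the log2 scale (adjusted p = 6.11e-09), from 119 ± 0.41 TPM to 0.751 ± 0.0996 TPM (SD, n = 2). MYCN fell from 23.1 ± 0.625 TPM to 0.365 ± 0.516 TPM (−4.19 ± 0.19, adjusted p = 2.34e-08). In all, 1094 genes were higher and 1655 lower among 16002 tested.

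The other largest decreases were those of GNG8 (−7.12 ± 1.36), PNMA2 (−7.01 ± 0.18), the proneural factor NEUROG2 (−6.97 ± 0.29), CNTFR (−6.80 ± 0.16) and INSM2 (−6.76 ± 0.22). The largest increases were those of IGFN1 (6.65 ± 0.17), the matrix metalloproteinase MMP3 (6.35 ± 0.30), CD109 (6.28 ± 0.16), the transcription factors OSR1 (6.17 ± 0.20) and ZIC2 (6.14 ± 0.17), and the protease inhibitor SERPINB7 (6.09 ± 0.20).

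Of 20 adrenergic transcription factors 11 fell, led by INSM2, HAND1 (−6.17) and ZNF536 (−5.72). HAND2 (−0.48 ± 0.06) and GATA3 (−0.18 ± 0.04) stayed under the minimum fold change, at 268 ± 11.5 and 260 ± 11.1 TPM in the resistant line. Of 15 catecholamine genes 11 fell, among them DDC (−6.43), SLC6A2, the noradrenaline transporter (−6.23), SCG3 (−5.97), CHGA (−5.95) and DBH (−5.67 ± 0.28). TH fell from 1.25 TPM to 0, at least 1.6-fold. With quantile normalization its fitted change was −0.88 and no longer passed. Of 20 neuronal genes 12 fell and 1 rose. The neurofilament genes NEFM (−6.71) and NEFL (−6.48), ELAVL3 (−6.68) and DCX (−6.06) fell most. The calls of the adrenergic and neuronal lists (adjusted p = 1.36e-06 and 3.14e-06) held with an estimated correlation (adjusted p = 0.0423 with an estimated correlation for both). That of the catecholamine list (adjusted p = 1.36e-06) did not, at adjusted p = 0.054 with an estimated correlation. In this comparison and in the next, every list had as many members called when adjusted over the list alone as over all genes.

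Of 24 mesenchymal transcription factors 14 rose and 1 fell. PRRX1 (4.61 ± 0.16), RUNX1 (4.40 ± 0.14), TBX18 (4.26 ± 0.11) and RUNX2 (4.23 ± 0.14) rose most, and FOSL1 rose by 2.73 ± 0.27. NOTCH2 (0.30 ± 0.13, adjusted p = 0.0749) was not called. Of 20 YAP and TAZ targets 7 rose, with AXL (3.67), LATS2 (3.49) and NT5E (2.19), and YAP1 itself rose by 2.09 ± 0.18. Of 21 cytoskeletal and transition genes 7 rose and 1 fell, led by CAV1 (5.43), ANXA1 (3.77), TWIST2 (2.85) and ACTA2 (1.54). Of 25 matrix and adhesion genes 7 rose and 2 fell. ITGA5 (2.46), CD44 (2.19) and THBS1 (1.86) rose, COL1A2 fell by 1.82, and FN1 (0.44 ± 0.12) and VIM (0.67 ± 0.08) stayed under the minimum fold change. These lists were called higher, with adjusted p of 1.57e-06 for the regulators, 0.00407 for YAP and TAZ targets, 0.00923 for cytoskeletal genes and 0.042 for matrix genes. None held: adjusted p = 0.0614 with an estimated correlation for the first and second of them, adjusted p = 0.199 with an estimated correlation for cytoskeletal genes and adjusted p = 0.217 with an estimated correlation for matrix genes.

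In the resistant line, of 35 interferon-stimulated genes 17 rose and 4 fell, led by IFIT3 (4.17), GBP1 (4.03), IFIT2 (3.84) and GBP2 (3.75). Of 20 genes of MHC class I presentation 8 rose and none fell. TAP1 rose by 2.17 ± 0.22, ERAP2 by 2.02 ± 0.10, HLA-E by 1.96 ± 0.15, PSMB8 by 1.86 ± 0.51 and NLRC5 by 1.44 ± 0.17. PSMB9 went from 0 to 2.10 TPM, at least 2.4-fold. HLA-C (0.88 ± 0.16), HLA-B (0.28 ± 0.35) and B2M (0.40 ± 0.06) changed less and were not called. The interferon and class I lists were called (adjusted p = 0.000111 and 0.000417) and held, each at adjusted p = 0.0423 with an estimated correlation. The call of PSMB8 was lost without SH-SY5Y replicate 2 (1.29, adjusted p = 0.0985) and without the first library of the resistant line (0.99, adjusted p = 0.0851). With only the 4 libraries compared it was lost at an unchanged fold change of 1.86 (adjusted p = 0.158). Of 16 nucleic acid sensing genes 5 rose and 1 fell. IFI16, a DNA sensor, rose by 5.64, the kinase IKBKE by 4.32, TLR3 by 3.42 and TMEM173, which encodes STING, by 2.64. The call (adjusted p = 0.00663) was lost at adjusted p = 0.0614 with an estimated correlation. Of 19 natural killer ligands and death receptors 8 rose and none fell, with FAS (3.11), RAET1G (2.85), ULBP3 (2.77 ± 0.42) and MICB (2.48). MICA went from 0 in both SH-SY5Y libraries to 2.44 ± 1.20 TPM, at least 2.1-fold. Of 18 cytokines and chemokines 7 rose and 1 fell. CXCL8 rose by 4.65, CXCL2 from 0 to 24.6 TPM (at least 13.6-fold) and CSF1 by 2.09. Of 15 NF-kB targets 7 rose and none fell, with CXCL8, PLAU (2.42), BIRC3 (2.16) and BCL3 (2.15). The natural killer and NF-kB lists were called (adjusted p = 0.00162 and 0.00072), each at adjusted p = 0.137 with an estimated correlation. The cytokine list was called at an adjusted p of 0.0135, and at adjusted p = 0.183 with an estimated correlation. Of 12 checkpoint genes 4 rose and 2 fell without a call for the list. PDCD1LG2 (3.35 ± 0.33) and CD274 (1.84 ± 0.31) rose and CD200 fell by 5.85 ± 0.15. With a pseudocount of 0.1 the call of CD274 was lost (1.90, adjusted p = 0.108). Of 6 MHC class II genes 1 rose, CTSS (1.25 ± 0.17).

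Among 19 receptor tyrosine kinases 5 rose and 8 fell, without a call for the list (adjusted p = 0.0626). MET, the receptor of hepatocyte growth factor, rose by 4.72 ± 0.13 and AXL by 3.67 ± 0.15, whereas ALK, RET (−4.65 ± 0.07) and NTRK2 (from 18.1 TPM to 0, at least 141.6-fold) fell. Of 20 RAS and MAPK outputs 2 rose and 2 fell: FOSL1 and PHLDA1 (1.88) rose, and DUSP6 (−1.18), a phosphatase induced by ERK, and MYC (−1.15) fell. Of 16 genes of drug efflux and lysosomes 2 rose, ABCC3 (1.95) among them, and the efflux pump gene ABCB1 fell by 1.86 ± 0.05 (list adjusted p = 0.00923, and adjusted p = 0.197 with an estimated correlation). Of 14 genes of the ATF4 stress response 1 rose, the cystine transporter SLC7A11 (1.69), and 4 fell, among them ATF3 (−3.41) and CHAC1 (−2.88). Of 14 hypoxia genes 1 rose, CA9 (2.72), and 3 fell, among them VEGFA (−2.13) and PDK1 (−1.55). The ATF4 and hypoxia lists were called lower (adjusted p = 0.00414 and 0.0238), at adjusted p = 0.0614 and 0.137 with an estimated correlation. Of 20 proliferation genes 1 fell, E2F1 (−1.0), and the list was called lower (adjusted p = 0.00407, and adjusted p = 0.33 with an estimated correlation). E2F1 lay at the minimum fold change and lost its call without SH-SY5Y replicate 2 (−0.98) or the first library of the resistant line (−1.0). Of 8 genes at or near MYCN only MYCN fell (list adjusted p = 0.0283, and adjusted p = 0.254 with an estimated correlation). None of 25 MYC targets was called (NOLC1 −0.16 ± 0.06). Of 19 cholesterol genes 2 fell, and of 11 Polycomb genes 1 fell, JARID2 (−1.10), with EZH2 at −0.28 ± 0.04. Markers of other cell types moved in the same comparison without a call for any of their lists. KRT19 (1.85), KRT8 (1.76) and KRT18 (1.59) rose among 7 epithelial markers, 3 of 11 neural crest and Schwann markers rose, among them SOX2 (1.53), and NGFR fell by 2.59. The call of SOX2 was lost with a pseudocount of 0.1 (1.55, adjusted p = 0.113). Of 10 leukocyte markers LCP1 (−4.34) and CD14 (from 3.36 TPM to 0, at least 2.4-fold) fell, and of 7 endothelial markers VWF rose by 1.71. None of 20 ribosomal protein genes was called. Of 10 replication histone genes, which normally lack a polyA tail, 4 rose and 2 fell, with HIST1H2AC at 1.67, HIST1H1C at 1.24 and HIST1H4C at −1.26.

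The third comparison set SH-EP against SH-SY5Y, 2 subclones of the same parental line that carry different lineage labels (n = 2 libraries each). Most adrenergic transcription factors, catecholamine genes and neuronal genes examined were lower in SH-EP, and many interferon-stimulated genes, MHC class I genes and cytokines were higher. The transcription factor gene TFAP2B fell by 7.06 ± 0.10 (adjusted p = 3.57e-12), from 422 ± 2.08 TPM to 2.17 ± 0.338 TPM (SD, n = 2). The WNT agonist RSPO3 rose by 7.50 ± 0.24 (adjusted p = 9.07e-10), from 0.14 to 205 TPM. In all, 1806 genes were higher and 2442 lower among 16002 tested.

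The other largest increases were those of the succinate receptor SUCNR1 (7.12), HOXA5 (7.12), the cancer-testis gene CTAG2 (7.09), the cytosolic DNA sensor AIM2 and GALNT5 (6.87). AIM2 went from 0 to 122 TPM, at least 90.3-fold. The other largest decreases were those of GNG8 (−7.45 ± 1.36), FAM163A (−7.43), RAB39A and PRRT4 (−7.10). RAB39A went from 138 TPM to 0, at least 100.7-fold lower.

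Of 20 adrenergic transcription factors 17 fell, with SIX3 (−6.95) and INSM2 (−6.84) after TFAP2B. HAND2 (−0.82 ± 0.06) and GATA3 (−0.55 ± 0.04) again stayed under the minimum fold change. Of 15 catecholamine genes 12 fell, led by SCG3 (−6.94), SLC6A2 (−6.68), CHGA (−6.57) and DDC (−6.54), with DBH at −5.36 ± 0.28. TH stayed near the floor in both lines, at 1.25 and 0.772 TPM, and its sign turned under quantile normalization (0.05). Of 20 neuronal genes 14 fell and 1 rose, with L1CAM (−6.85), INA (−6.84), DCX (−6.83) and ELAVL3 (−6.76). The adrenergic and neuronal lists (adjusted p = 7.82e-09 and 2.24e-05) held at adjusted p = 0.0249 with an estimated correlation. The catecholamine list (adjusted p = 5.05e-05) did not, at adjusted p = 0.121 with an estimated correlation. ALK fell by 5.27 ± 0.23, and MYCN went from 23.1 TPM to 0 in both SH-EP libraries, at least 23.9-fold lower.

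Of 24 mesenchymal transcription factors 12 rose and 1 fell. PRRX1 (6.23 ± 0.16), RUNX2 (5.59) and RUNX1 (4.67) rose and AEBP1 fell by 4.59, and FOSL1 rose by 3.10 ± 0.27. Of 25 matrix and adhesion genes 10 rose and 3 fell, led by COL6A3 (5.66), POSTN (5.33), COL5A2 (4.46) and TGFBI (4.04), and CD44 rose by 2.45. FN1 (0.88 ± 0.12) stayed under the minimum fold change, and passed it with the estimate of uncollapsed reads (1.05). Both lists were called (adjusted p = 4.1e-05 and 0.00259), each at adjusted p = 0.124 with an estimated correlation. Of 21 cytoskeletal genes 5 rose and 1 fell without a call for the list. CAV1 (5.40), ANXA1 (4.09), TWIST2 (3.67) and TPM2 (1.94) rose, and VIM (0.33 ± 0.08) stayed under the minimum. Of 20 YAP and TAZ targets 7 rose and 3 fell, also without a call for the list. AXL (3.88), LATS2 (3.05) and CTGF (2.99) rose, YAP1 rose by 2.51 ± 0.18, and ANKRD1 fell by 3.23 ± 0.43. With a pseudocount of 0.1 the call of ANKRD1 was lost (−3.27, adjusted p = 0.0719).

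Of 20 genes of MHC class I presentation 11 rose and none fell. ERAP2 (3.89), PSMB8 (3.64 ± 0.51), TAP1 (2.56 ± 0.22), HLA-E (2.40), HLA-B (2.02 ± 0.35) and HLA-C (1.86 ± 0.16) rose. PSMB9 went from 0 to 4.11 ± 1.02 TPM, at least 4.7-fold, and NLRC5 rose by 1.43 ± 0.17. B2M (0.54 ± 0.06) was not called. Of 35 interferon-stimulated genes 19 rose and 2 fell, with GBP1 (4.84), IFIT3 (4.84), TRIM22 (4.70) and IFIT2 (4.48). Both lists (adjusted p = 4.42e-05 and 2.24e-05) held at adjusted p = 0.0249 with an estimated correlation. Of 16 nucleic acid sensing genes 7 rose and 2 fell. After AIM2, IFI16 (5.88), TMEM173 (5.75) and IKBKE (4.22) rose most, and TLR3 rose by 3.24 ± 0.18 (list adjusted p = 0.0141, and adjusted p = 0.123 with an estimated correlation). Of 19 natural killer ligands 11 rose and 3 fell. CLEC2B went from 0 to 77.0 TPM (at least 75-fold), MICA from 0 to 28.4 ± 1.70 TPM (at least 25-fold), and RAET1E (4.44), MICB (4.14) and ULBP3 (3.49) rose (list adjusted p = 0.00903, and adjusted p = 0.214 with an estimated correlation). Of 18 cytokines and chemokines 12 rose and 3 fell. TNFSF10, the death ligand TRAIL, rose by 6.32, CXCL8 by 5.42 and LIF by 3.57, and CCL2 fell by 5.24 (list adjusted p = 0.00903, and adjusted p = 0.189 with an estimated correlation). Among lists without a call, 3 of 6 MHC class II genes rose, HLA-DPB1 (from 0 to 5.19 TPM, at least 5.3-fold), HLA-DPA1 (2.41) and CTSS (2.07). Of 12 checkpoint genes TNFRSF14 (3.11), PDCD1LG2 (3.06) and NT5E (2.20) rose and CD200 went to 0, at least 87.6-fold lower. CD274 (0.78 ± 0.31) stayed under the minimum fold change, and passed it with quantile normalization (1.03). Of 15 NF-kB targets 5 rose, BCL3 (2.57) among them, and 3 fell, ICAM1 (−2.46) among them.

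The list of 16 genes of drug efflux and lysosomes was called higher with 3 risen members, TFEB (1.52) and CTSL (1.15) among them, and ABCB1 fell by 1.42 (adjusted p = 0.0105, and adjusted p = 0.214 with an estimated correlation). The genes around MYCN were called lower through MYCN and FAM49A (−3.28), 2 of 8 (adjusted p = 0.0164, and adjusted p = 0.227 with an estimated correlation). The other lists were not called. Of 19 receptor tyrosine kinases 4 rose, MET (5.36 ± 0.13) and AXL among them, and 8 fell, RET (−6.79 ± 0.07) and ALK among them. Of 20 RAS and MAPK outputs 4 rose, EPHA4 (from 0 to 28.7 TPM, at least 80-fold) and FOSL1 among them, and 4 fell, with MYC at −1.91. Of 25 MYC targets only TERT fell (−2.42). No proliferation gene of 20 was called (TOP2A −0.09 ± 0.06, MKI67 −0.09 ± 0.04), and no Polycomb gene of 11 (EZH2 −0.44 ± 0.04). Of 19 cholesterol genes 1 rose, and DHCR7, the last enzyme of the pathway, fell by 6.00. Of 14 ATF4 genes SLC7A11 rose by 3.11 and 4 fell, with ATF3 (−2.88) and CHAC1 (−2.53). Of 14 hypoxia genes 2 rose, CA9 (5.01) among them, and EGLN3 fell by 1.16. Markers of other cell types differed too. Of 7 epithelial markers KRT19 (4.34), KRT8 (4.09) and KRT18 (2.02) rose and 1 fell, and of 7 endothelial markers EMCN (6.27) and TIE1 (2.90) rose. Of 11 neural crest and Schwann markers 3 rose, S100B (4.91) and TFAP2A (3.50) among them, and 3 fell, SOX2 (−5.23) and NGFR (−2.86) among them. Of 10 leukocyte markers 3 rose, with CSF1R at 2.88 and LCP1 at 2.07, and 2 fell. No ribosomal protein gene of 20 was called, and of 10 replication histone genes 1 fell, HIST1H4C (−1.27).

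**Figure D2:**
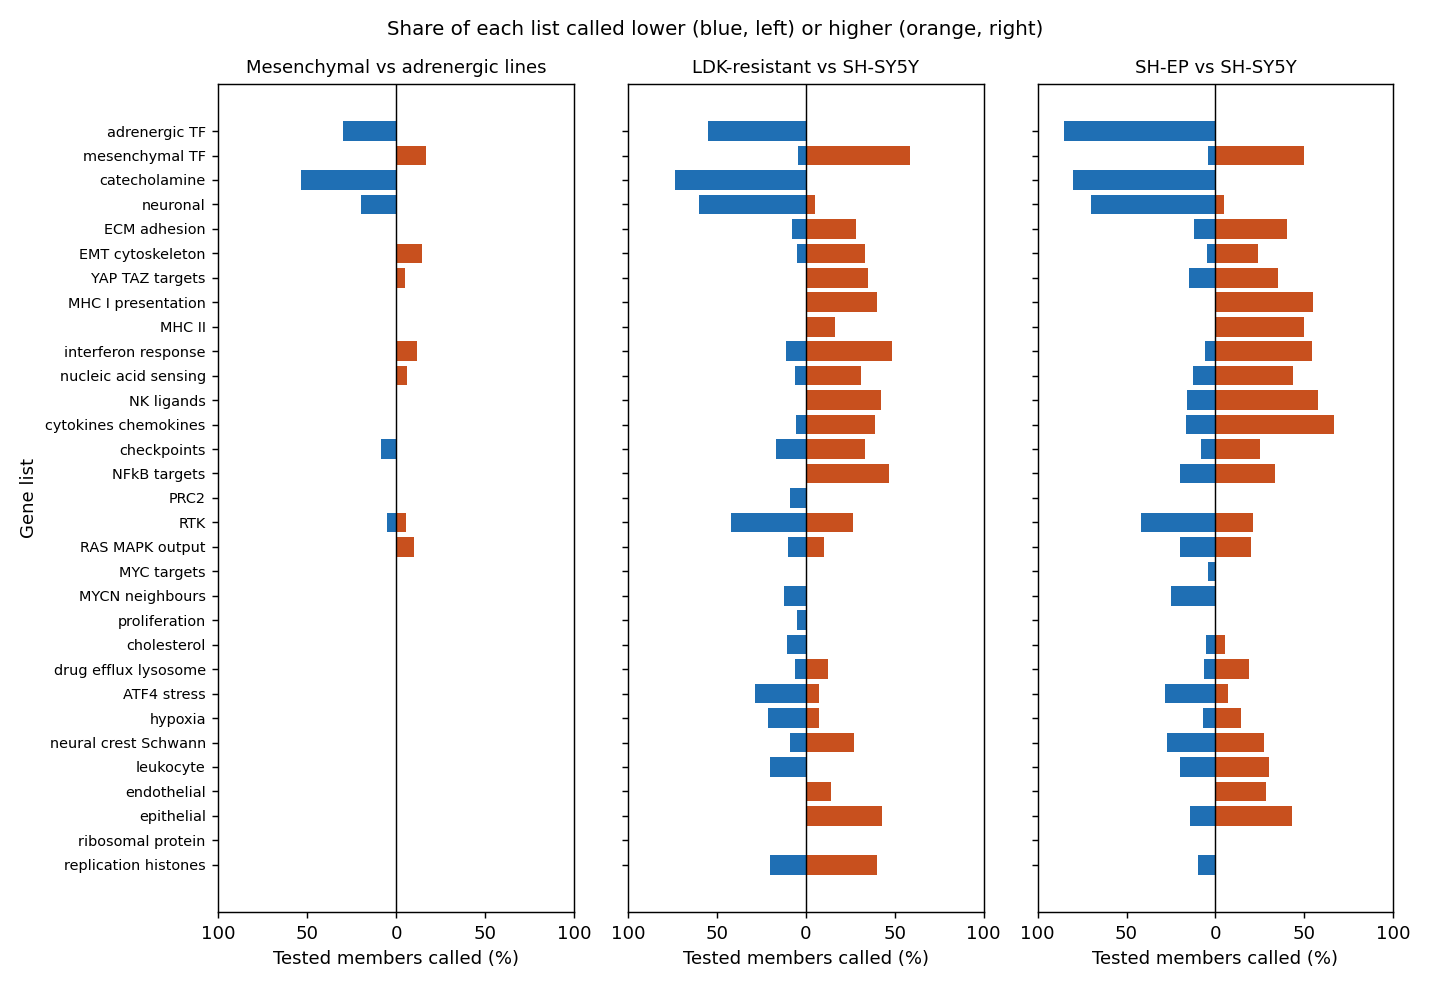
Share of the tested members of each gene list (horizontal axis, percent) that was called lower (blue, to the left) or higher (orange, to the right) in the 3 comparisons. Catecholamine genes fell in each comparison, with 8, 11 and 12 of 15 called, and MHC class I genes were called higher in the 2 comparisons with SH-SY5Y, with 8 and 11 of 20.

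The resistant line and SH-EP were then compared in what they share. Of the genes called against SH-SY5Y, 693 were higher and 1315 lower in both, which is 63.3% and 79.5% of the calls of the resistant line, while 93 and 45 of its higher and lower genes were called the other way in SH-EP. CAV1, AXL, PRRX1, TLR3, IFI16 and MET were higher in both, and ALK, MYCN, DBH, CHGA, INSM2 and RET lower in both. Both comparisons use the same SH-SY5Y libraries. With unchanged groups simulated against these libraries 0 genes were called in both. Few or no shared calls were bound to follow, since no group was changed, so the simulation covers only the spread between libraries. Independent lists of these sizes would share 123 and 253. The fold changes correlated at 0.661 across genes, against 0.496 in the simulation, and their covariance was 1.27, against 0.017. With the SH-SY5Y libraries split after these results were seen, so that each comparison used its own, 652 or 666 genes were higher and 1263 or 1265 lower in both. The correlation was then 0.644 or 0.641, by which library went to which comparison. Genes whose level is peculiar to SH-SY5Y would differ in the same direction in both comparisons. The simulation, the independent lists and the split do not account for such genes. The shared counts and the correlation therefore cannot tell them from changes common to the resistant line and SH-EP.

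Where the 2 lines differed from each other was tested directly for the 26 genes fixed in advance, by the contrast of SH-EP with the resistant line. Of these, 5 differed at the thresholds used here, and 4 of them are given. CD274 was lower in SH-EP (log2 difference −1.06 ± 0.31, adjusted p = 0.0166). MICA (3.14 ± 0.22), HLA-B (1.74 ± 0.35) and PRRX1 (1.62 ± 0.16) were higher in SH-EP (adjusted p = 8.84e-07, 0.00198 and 1.03e-05).

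To ask whether the resistant line differs from its parent in the genes that separate the lineages elsewhere, its fold changes were set against those of CHP-212 and SH-EP relative to Kelly and NBL-S, 4 lines that share no library with it. Pearson's r across 16002 genes was 0.538 and Spearman's rho 0.484. Of the 1094 genes higher in the resistant line 81.6% were also higher in the other mesenchymal lines, with a median log2 difference of 1.38, and of the 1655 lower genes 81.0% were also lower, with a median of −1.30. Of all genes 48.9% lay above 0. The other pairings of the same 4 lines also gave a positive r when SH-EP, from the tumour that gave SH-SY5Y, was in the pair subtracted from: 0.194 for SH-EP and NBL-S minus CHP-212 and Kelly, and 0.253 for SH-EP and Kelly minus CHP-212 and NBL-S. In these 2 pairings, in that order, 68.4% and 67.3% of the higher genes and 60.1% and 67.3% of the lower genes had the same sign, and these shares rather than 48.9% are the ones to set beside 81.6% and 81.0%. The sign of r depends on which pair is subtracted. Genes are not independent replicates, so no p was computed.

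**Figure D3:**
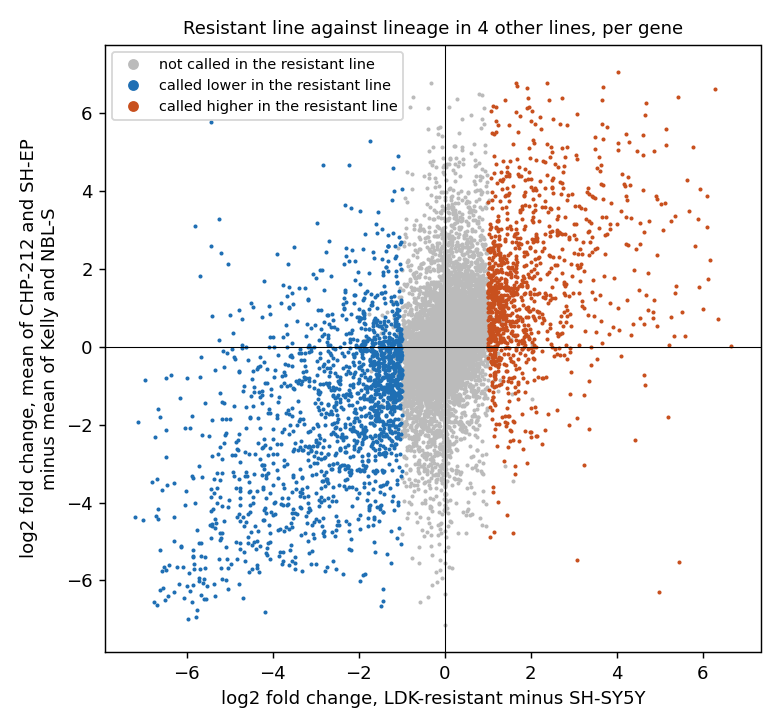
Log2 fold change of each of 16002 genes in the resistant line relative to SH-SY5Y (horizontal axis) and in CHP-212 and SH-EP relative to Kelly and NBL-S (vertical axis), with 1 point per gene coloured by its call in the resistant line. Called genes lie mostly in the lower left and upper right, with 81.6% of the higher and 81.0% of the lower genes on the same side of 0 in the other lines.

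The last comparison asked which genes go with the MYCN label, with lineage as a covariate (2 amplified lines against 4). MYCN (GRCh38 chromosome 2, 15940564 to 15947007) stood at 738 ± 9.06 TPM in Kelly and 657 ± 23.2 TPM in CHP-212 (SD, n = 2). NBL-S, labelled not amplified, reached 295 ± 6.24 TPM, SH-SY5Y 23.1 ± 0.625 TPM, the resistant line 0.365 ± 0.516 TPM, and SH-EP was at 0 in both libraries. The fitted difference was 6.15 ± 1.65 on the log2 scale and was not called (adjusted p = 0.439). The 4 lines without amplification spread over nearly the whole range. MYCN was the highest gene of both Kelly libraries, at 0.806 and 0.807 recovered reads per exonic base. If reads were collapsed to 1 per start position, the gap in MYCN between Kelly and NBL-S is compressed. The other genes of the list around MYCN, which lie on chromosome 2 between 10439968 (ODC1) and 16666331 (FAM49A), differed less and none was called. DDX1 (chromosome 2, 15591178 to 15631111) was at 591 ± 1.16 TPM in CHP-212 and 266 ± 6.28 TPM in Kelly, against 177 to 279 TPM in the other lines (0.93 ± 0.37, adjusted p = 0.485). LPIN1 differed by 0.62 ± 0.42, TRIB2 by 0.39 ± 0.48, the MYC target ODC1 by 0.35 ± 0.10, NBAS by 0.27 ± 0.15, ROCK2 by 0.16 ± 0.12 and FAM49A by −0.46 ± 1.53. Genes called lower were 6 and genes called higher 0, with 1647 at an unadjusted p under 0.05 in either direction. TSPYL5 (−6.96 ± 0.36, adjusted p = 0.0241), S100A10 (−6.89 ± 0.42, adjusted p = 0.0306) and FUCA2 (−6.34 ± 0.30, adjusted p = 0.0227) had the largest decreases. FUCA2, which encodes a secreted fucosidase, was at 0.652 and 0.812 TPM in Kelly and CHP-212 and at 91.6 to 181 TPM in the other lines. Without limma's trend no gene was called lower, and with all libraries and a correlation between duplicates 45 were higher and 120 lower, MYCN among them (adjusted p = 0.0211).

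The main genes lie as follows in GRCh38 with GENCODE release 29 gene models. ALK spans 29192774 to 29921566 on chromosome 2, DBH 133635348 to 133659344 on chromosome 9, PRRX1 170662728 to 170739419 on chromosome 1, AXL 41219203 to 41261766 on chromosome 19, TLR3 186069152 to 186088069 on chromosome 4 and MICA 31399784 to 31415315 on chromosome 6. PSMB9 (32844136 to 32859585) and TAP1 (32845209 to 32853978) overlap on chromosome 6, and KRT8 (52897187 to 52949954) and KRT18 (52948871 to 52952901) overlap on chromosome 12. Values are sums over the exons of a gene.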

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

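All tests of explanations in this part were chosen after the results they address had been seen. Whether the lineage difference was the same in the MYCN-amplified lines (CHP-212 minus Kelly) as in the other lines (SH-EP and the resistant line minus SH-SY5Y and NBL-S) was tested for the 26 genes fixed in advance, as an interaction in the fit of 12 libraries, and 13 genes differed, of which 12 are given. For MYCN the lineage difference was −0.17 in the amplified pair and −6.20 in the other lines, so that the difference of differences was 6.03. For NOTCH2 (1.87), FOSL1 (1.76) and VIM (1.64) the increase was larger in the amplified pair. The signed difference was lower in that pair for FN1 (−5.16), PRRX1 (−5.11), ULBP3 (−3.27), MICA (−2.84), CD44 (−2.14), CD274 (−1.71), PSMB9 (−1.61) and TAP1 (−1.54). The amplified side holds 1 line per lineage and the spread is that of duplicates, so these values show how CHP-212 and Kelly differ from the other lines and not an effect of MYCN. For PRRX1, CHP-212 exceeded Kelly by 1.41, whereas the other mesenchymal lines exceeded their counterparts by 6.53. Among 118 groups of 6 libraries examined for a library far from the rest, 1 stood out: NBL-S replicate 1, with 4.33 M recovered reads (4327031), lay below the other adrenergic libraries. Chance gives about 1 in 20 such groups where the 6 values are independent. Here they are duplicates of 3 lines, so that rate does not apply, and a line whose 2 libraries both deviate would hardly be flagged.

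The lineage comparison called 265 genes, and the highest count of the other splits of the 6 lines into 3 and 3 was 1. The real split was the 1 of 10 splits with as many called genes, and 10 splits are too few for a share under 0.05. Cell lines also differ in patient, stage and culture history, which were not tested.

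The highest values spanned a narrow range, with a top of 799.1 TPM and 0.69% or less of a library in its 10 highest genes. Ribosomal protein transcripts were not left out of the table, since all 20 genes of the fixed list were listed. Mitochondrially encoded genes, of which 0 are listed, were left out, and whether this bears on the range was not tested. The values are consistent with reads collapsed to 1 per start position: the highest recovered reads per exonic base in any library were 0.861, under 1, and in 6 of 6 lines the less deep duplicate was relatively higher at the top of the scale than in its middle. Such collapsing may compress fold changes of abundant genes, and no processing note names it. No biological explanation was tested.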

How the results depend on the processing

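The tests chosen after the data were seen were those with the estimate of uncollapsed reads, with duplicateCorrelation plus a replicate block, in the 4 lines from 4 patients, with an own SH-SY5Y library per comparison, and camera on 12 libraries. Where no cause is named, the cause was not tested. Every count of calls stayed within 1.5 times its value under a pseudocount of 0.1, both filters, all scalings, a replicate block and uncollapsed reads. The replicate block left 61 higher and 204 lower genes between the lineages. That outcome was fixed in advance, since the block cancels when the 2 libraries of a line are averaged. Quantile normalization evened the split of calls, to 1414 higher and 1444 lower in the resistant line and to 2232 and 2191 in SH-EP. Without a minimum fold change, which calls more genes by construction, the resistant line had 4471 higher and 4254 lower genes and SH-EP 5154 and 5272. The fit with duplicateCorrelation used all libraries and 1 correlation within lines for all genes, 0.945 for the lineages and 0.929 for MYCN. It gave 451 higher and 602 lower genes between the lineages and 45 and 120 for MYCN. With a replicate block added these were 401 and 558, and 28 and 87. The spread between duplicates alone leaves out the spread between lines, which raises counts by construction. It gave 1785 and 2007, and 1112 and 1500. Without limma's trend 0 genes were lower for MYCN (1406 at an unadjusted p under 0.05). Leaving out a line gave 8 higher and 42 lower lineage genes without Kelly, 22 and 106 without the resistant line, 230 higher without SH-SY5Y, 73 and 244 without CHP-212, 0 and 19 without SH-EP (1790 at an unadjusted p under 0.05) and 0 and 0 without NBL-S (1841). In the 4 lines from 4 patients limma called 0 and 0 (2204). Lists called numbered 18, 18 and 12 in the lineage, resistant and SH-EP comparisons with the preset correlation, 0, 4 and 4 with an estimated correlation and 6, 28 and 26 by fry.

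Leaving out 1 library at a time gave 57 to 67 higher and 190 to 206 lower lineage genes, 1029 to 1135 and 1581 to 1711 in the resistant line, 1754 to 1808 and 2379 to 2475 in SH-EP, and 0 and 5 to 6 for MYCN. Genes shared by both lines were 659 to 703 and 1262 to 1336, the correlation with the other lines was 0.531 to 0.538, and lists called were 17 to 18, 17 to 19 and 12 to 14. A lone library was assumed to vary like the duplicates of the other lines. Signs turned for HLA-B in the resistant line (−0.17 to 0.74) and CALR between the lineages (−0.01 to 0.07), neither of them called. Signs also turned for TH in SH-EP with quantile normalization (0.05), and between the lineages for TH without Kelly (0.65) and for PTPRC (−0.73) and TEK (−1.12) without CHP-212. Of the 77 lineage genes named, 13 were the same under all 15 other alternatives, 35 lost their call in at least 1 and 29 gained it in at least 1. A pseudocount of 0.1 ended 9 of their calls, those of FOSL1, TBX18, GBP1, IFIT2, DDC, HAND1, MYOF, AXL and TWIST2. The depth of 4327031 to 7590311 reads limits genes near the floor, such as TH in SH-SY5Y and SH-EP. Rescaling on ERCC entries was not run, since 0 are listed. Rescaling to a fixed total moved no count of called genes by more than 1. This was bound to follow, since the deposited values already add up to nearly the same total in every library.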

Other observations

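The test of HOX genes in this part was chosen after HOXA5 had been seen among the largest increases in SH-EP. The genes singled out in the next sentences were named after their values were seen. The leukocyte antigen gene PTPRC was at 191.7 ± 7.27 TPM (SD, n = 2) in CHP-212 and at 1.26 TPM or less in the other lines, and the endothelial receptor gene TEK at 351.9 ± 8.3 TPM in CHP-212 and 3.71 TPM or less elsewhere. NGFR was at 327 TPM in CHP-212 and 174 TPM in NBL-S. EMCN was at 116 ± 2.12 TPM in SH-EP and at 0.677 TPM or less in the other lines. None of the marker lists that hold these genes was called in the lineage comparison.

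HOXA5 stood at 171.5 ± 3.72 TPM in SH-EP and at 0.738 TPM or less in the other lines. HOX genes as a family may be higher in SH-EP than in SH-SY5Y: 16 of 33 tested HOX genes were called higher and 6 lower, a share of 48.5% higher against 11.3% of all tested genes (two-sided Fisher exact test, p = 1.15e-07). Genes of a HOX cluster are regulated together and are not independent, so this p overstates the evidence. In the resistant line 0 HOX genes were called higher by limma, 0% against 6.8% of all tested genes (Fisher exact test, p = 0.168), and 6 were called lower, which was not tested. At 5 TPM or more there were 23 of 33 HOX genes in SH-EP, 14 in SH-SY5Y, 11 in Kelly, 11 in NBL-S, 10 in the resistant line and 6 in CHP-212.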
